A study of Atractylodes lancea with 6 samples.

How the data were processed

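Transcript levels were measured by paired-end RNA sequencing of 6 libraries from Atractylodes root or rhizome tissue, 3 labelled AJ and 3 labelled AR. The series text places the collection of both plants in the same garden. Per the labels' protocols, polyadenylated RNA was converted to strand-specific libraries with dUTP marking. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR without their roles. The deposited table's row names are those of a Trinity de novo assembly, which does not match the use of a genome aligner, and the assembly settings and the counting tool are not given in the sources used here. How reads from near-identical copies were shared is therefore unknown, and genes of multigene families, fragments of one transcript and other assembled copies are uncertain as single units.

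The deposited file held 84109 genes with a length in bases (median 456, range 201 to 15176), annotation text and 2 value columns per library. The estimated counts per gene were made by the authors and are not normalized, and about 10% of them are not whole numbers. The TPM values (transcript levels scaled to a common total per library) were also deposited by the authors. That unit was inferred from the values, which sum to 991017 to 994699 per library, since the header gives no unit. No gene had a total count of 0, and 40354 genes had a protein name from at least one of the annotation sources. A gene length is the length of the assembled sequence, not of a complete transcript. All value columns were mapped to a library by name.

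Estimated counts were rounded to whole numbers, filtered with filterByExpr defaults and scaled with TMM (edgeR 4.0.16, R 4.3.3). The groups were compared with edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05, and a second count also asked for an absolute log2 fold change of at least 1. Fold changes are AJ relative to AR, so negative values are lower in AJ. Their standard errors were taken as the absolute log2 fold change over the square root of the F statistic. Such an error can understate counting error where a group has few counts. CPM values use the TMM-scaled library sizes. Where a group had no count for a gene, the fold is a lower bound against a floor of 3 counts over the group. For the 14 genes named by rule with such a bound, leaving out a library of the group without counts lowers it 1.41 to 1.59 times, since the same floor is then set against fewer counts. With 1 to 3 counts in a group, the ratio of counts is given with an exact binomial 95% interval. These bounds and intervals cover counting error only, since reads carried no molecular identifiers. The libraries held 15680457 to 20528572 counts, and some levels named in the text rest on few counts, such as 6 over the AJ libraries for QH6 and for the CASP-like protein 1D1.

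Fixed before the data were examined were 23 gene lists (11 core and 12 other), matched on protein name, symbol and ortholog text. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, over lists with at least 5 tested members and with Benjamini-Hochberg adjustment over the 23 lists. Genes named in the text were also chosen by a rule fixed then. It took the 6 largest differences in each direction among genes past the threshold with no overlap between groups, at least 10 CPM in the higher group and a named protein. It further took the 2 members of each core list and the 1 member of each other list with the smallest adjusted p, and the 3 most abundant genes of each group. Genes named outside the rule are marked where they appear.

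The test was tried on simulated counts for the 44406 genes of the AJ and AR comparison, drawn with the real means and library sizes and with 200 changed genes. It recovered 0%, 0%, 14% and 24% of genes changed by 2-, 4-, 8- and 16-fold, 50 genes each. In that run 5% of its calls were false, a share that rests on few calls, and it made 0 calls when no gene was changed. The simulation gave both groups the same spread, while AR varied more than AJ in the data. It therefore does not bear on error control under unequal spread. So when few genes differ, most changes are missed in this design, even those of 16-fold. An exact permutation test of 3 against 3 values cannot give a two-sided p under 0.1.

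Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no low-count filter, and a filter of at least 50 counts in 3 libraries. The others were DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) with a mean of at least 1 in a group, the same with a pseudocount of 0.1 or without the filter, each replicate left out, the replicate number as a block, and a test against a fold of 1.5. Alternatives added after seeing the data were group variance weights in limma-voom, counts summed per assembly component or per best protein hit, narrower lists, and list tests among annotated genes only. KEGG pathways with at least 10 tested genes were tested with a one-sided Fisher's exact test per direction, also chosen after the data were seen. Metabolite data mentioned in the series title were not analysed here.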

Results

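RNA sequencing was carried out on underground tissue, labelled root and titled as rhizome, from 2 groups of Atractylodes plants called AJ and AR, with 3 libraries in each group. Atractylodes is a genus of the daisy family whose rhizomes are used as herbal drugs and are rich in volatile terpenoids. The series text names A. chinensis and A. japonica as the plants and a comparison of their components as its aim. The organism label gives Atractylodes lancea for all 6 samples, which differs from both names. The labels do not say which group is which plant, so the groups keep their label names here. The table held 84109 genes of a de novo transcriptome assembly, each with estimated counts and TPM in the 6 libraries. Total counts were 19658265, 20299708 and 20528572 in AJ replicates 1, 2 and 3, and 15680457, 17599372 and 18223582 in AR replicates 1, 2 and 3. The labels do not state that the 3 libraries of a group came from separate plants, so the p-values measure the spread between these libraries, which may be partly technical.

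The first principal component of log2 CPM separated the AJ from the AR libraries and held 59.7% of the variance. The second held 18.8% and set AR replicate 2 apart from the other AR libraries. Across genes, Pearson correlations of log2 CPM were 0.90 to 0.95 between AJ libraries, 0.81 to 0.87 between AR libraries and 0.65 to 0.70 between groups. Genes are not independent replicates, and these correlations describe the libraries only. The biological coefficient of variation, the spread between replicates beyond counting error, was 0.419 within AJ and 0.769 within AR. Replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom of at least 24.3 over genes with 10 or more counts in the pair, so each was counted as a separate library.

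**Figure D1:**
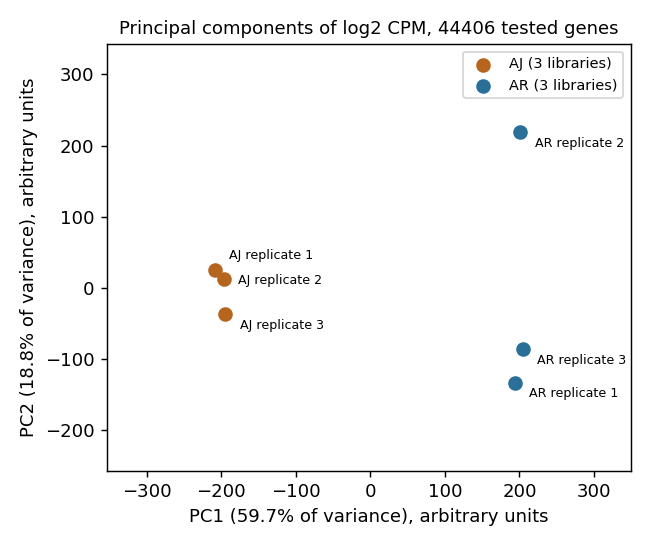
Principal components of log2 CPM over the 44406 tested genes, with PC1 (59.7% of variance) on the x axis and PC2 (18.8%) on the y axis in arbitrary units, and 1 point per library. The 3 AJ libraries lie together on the left, the 3 AR libraries lie on the right, and AR replicate 2 lies apart from the other AR libraries on PC2.

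The comparison of AJ with AR asked which genes and pathways of these underground organs differed in expression between the plants. Of 17 tested terpene synthases 7 were lower and 1 was higher in AJ, and of 30 tested CYP71-type oxygenases 13 were lower and 2 were higher. Both lists passed camera at its preset correlation, and each had an adjusted p = 0.57 with an estimated correlation. A beta-pinene synthase reached 445 ± 31.5 CPM in AR (SD, n = 3) against 0.0955 ± 0.0114 CPM in AJ. The AJ level rests on 6 counts over the group, so its SD understates the counting error. In the other direction, a type III polyketide synthase had 110 ± 4.31 CPM in AJ (SD, n = 3) and no count in AR. The most abundant transcripts, among them an HSP70 and a root allergen, did not pass the test.

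Of 44406 genes tested with edgeR's quasi-likelihood test, 7962 (17.9%) differed at a Benjamini-Hochberg adjusted p under 0.05, with 4577 higher in AJ and 3385 higher in AR. Among the 29491 annotated genes tested, 2038 were higher in AJ and 2449 higher in AR, and sums per best protein hit gave 1078 and 992. With a fold of at least 2 as well, 7600 genes passed, 4490 higher in AJ and 3110 higher in AR. The libraries of the groups did not overlap for 42.3% of tested genes, where chance gives 10%. Of the genes higher in AJ, 44.4% had a protein hit, against 72.3% of those higher in AR and 68.6% of those not called. Of the genes higher in AJ, 1893 had at most 3 counts over the 3 AR libraries, and 697 of the genes higher in AR had at most 3 counts over the AJ libraries. The count fell to 250, 55 and 117 without AJ replicate 1, 2 or 3, was 4521 with no low-count filter and 4518 with a stricter one, and was 13255 with DESeq2. On log2(TPM + 1) values limma called 8468 genes, 4771 of them among the 7962, with 6152 higher in AJ and 2316 higher in AR, and sums over assembly components gave 3574 calls in place of 7962.

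Terpene synthases, which form the carbon skeletons of volatile terpenoids, had 17 tested members, of which 7 were higher in AR, 1 was higher in AJ and 9 did not pass. Adjusted over the list alone, the same numbers passed in each direction, 7 and 1. The beta-pinene synthase QH6 (TRINITY_DN24163_c2_g1) had a log2 fold change of -12.10 ± 0.30 (SE, adjusted p = 0.00022). Its AJ level rests on 6 counts over the group, so this SE understates the counting error of the fold. The beta-caryophyllene synthase QHS1 (TRINITY_DN30204_c2_g1) had 14997 counts over the AR libraries and 1 over the AJ libraries, a ratio of 19900 with an exact 95% counting interval of 3570 to 786000. Its levels varied widely within AR, at 315 ± 361 CPM (SD, n = 3), and without AR replicate 2 their mean was 107 CPM and the ratio 7050 (interval 1260 to 278000). Without AJ replicate 1, which held its only AJ count, it was at least 4700-fold lower in AJ. A neighbouring fragment of the same assembly component, ECS1 (TRINITY_DN30204_c2_g4), was at least 1690-fold lower in AJ against a floor of 3 counts over the group, and at least 561-fold lower without AR replicate 2. The list stood lower in AJ than other genes by camera (median log2 fold change -2.15, adjusted p = 0.0079). With an estimated correlation its adjusted p = 0.57. Summed over all 25 matched genes, terpene synthase counts were 255 ± 41.9 CPM in AJ and 2410 ± 1720 CPM in AR (SD, n = 3), and AR replicate 2 alone had 4370 CPM.

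The list of CYP71-type cytochrome P450 oxygenases, a class that oxidises sesquiterpenes among other substrates, had 30 tested members, of which 13 were higher in AR, 2 were higher in AJ and 15 did not pass. Adjusted over the list alone, 14 were higher in AR and 4 higher in AJ. CYP71B37 (TRINITY_DN16707_c0_g1) had no count in AJ and 158 ± 69.1 CPM in AR (SD, n = 3), at least 3240-fold lower in AJ, or at least 2050-fold without AJ replicate 3. CYP716B2 (TRINITY_DN25077_c0_g1), annotated as a beta-amyrin 28-oxidase, had 423 ± 512 CPM in AR (SD, n = 3) and a log2 fold change of -9.08 ± 1.33 (SE, adjusted p = 0.012). Without AR replicate 2 its AR mean was 129 CPM and its log2 fold change -7.36. It belongs to the triterpene-oxidising CYP716 family, which the list's pattern also matched together with CYP714 names. The list's median log2 fold change was -2.61, with an adjusted p of 0.0013 by camera and an adjusted p = 0.57 with an estimated correlation.

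Among the steps that supply terpenoid precursors, more members were higher in AR than in AJ. Of 21 tested prenyl diphosphate synthases and isomerases, 6 were higher in AR, none was higher in AJ and 15 did not pass. Adjusted over the list alone, 7 were higher in AR. GGPS1 (TRINITY_DN13725_c0_g1), a geranylgeranyl diphosphate synthase, had 0.486 ± 0.187 CPM in AJ and 9.37 ± 4 CPM in AR (SD, n = 3), a log2 fold change of -4.26 ± 0.54 (SE, adjusted p = 0.01). The fragment SPS1 (TRINITY_DN27540_c0_g1) is annotated as a geranyl pyrophosphate synthase by one source and as a mitochondrial solanesyl-diphosphate synthase by another. With 5 counts over the AJ libraries, it had a log2 fold change of -5.78 ± 0.98 (SE). This was -5.19 without AJ replicate 1 and -6.41 without AJ replicate 2, and in neither case did the gene pass. This list passed by camera with an adjusted p of 0.0079, and its adjusted p = 0.57 with an estimated correlation. The list also took in a few proteins that share short symbols, such as a zinc finger protein.

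Of 23 tested genes of the plastid MEP pathway, 4 were higher in AR, 2 were higher in AJ and 17 did not pass. Adjusted over the list alone, 7 were higher in AR and 3 higher in AJ. A 1-deoxy-D-xylulose-5-phosphate synthase (TRINITY_DN21850_c3_g2), the entry enzyme of this pathway, had 1.99 ± 0.734 CPM in AJ and 187 ± 115 CPM in AR (SD, n = 3), a log2 fold change of -6.55 ± 0.71 (SE, adjusted p = 0.0081). DXR (TRINITY_DN18453_c0_g1), the next enzyme, had a log2 fold change of -2.11 ± 0.32 (SE). Of 22 tested genes of the cytosolic mevalonate pathway, 2 were higher in AR and 20 did not pass, both over all genes and adjusted over the list alone. They were the decarboxylase MVD2 (TRINITY_DN17155_c2_g1, log2 fold change -4.30 ± 0.74, SE) and the acetyl-CoA acetyltransferase AAT1 (TRINITY_DN29395_c0_g2, -1.93 ± 0.39, SE). Without AR replicate 2 the log2 fold change of MVD2 was -3.55, and on log2(TPM + 1) values MVD2 did not pass (adjusted p = 0.078). Neither list passed as a whole, with adjusted p = 0.19 for the MEP pathway and adjusted p = 0.061 for the mevalonate pathway. The median log2 fold changes were -0.60 and -1.18, while the mean of the MEP list was 0.00. For the mevalonate pathway, 2 of 22 is near the 3385 of all 44406 tested genes that were higher in AR.

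Of 37 tested genes of squalene, triterpene and sterol synthesis, 7 were higher in AR, 3 were higher in AJ and 27 did not pass (adjusted p = 0.31 as a list, median log2 fold change -0.48). Adjusted over the list alone, 7 were higher in AR and 4 higher in AJ. A cycloartenol synthase (TRINITY_DN32735_c1_g1), which closes the ring system of plant sterols, had a log2 fold change of -3.05 ± 0.47 (SE). A squalene monooxygenase (TRINITY_DN27574_c0_g3) had 59 ± 74.7 CPM in AR (SD, n = 3) and a log2 fold change of -7.15 ± 1.22 (SE). Without AR replicate 2 its AR mean was 16 CPM and its log2 fold change -5.25, and with limma-voom it did not pass (adjusted p = 0.072).

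**Figure D2:**
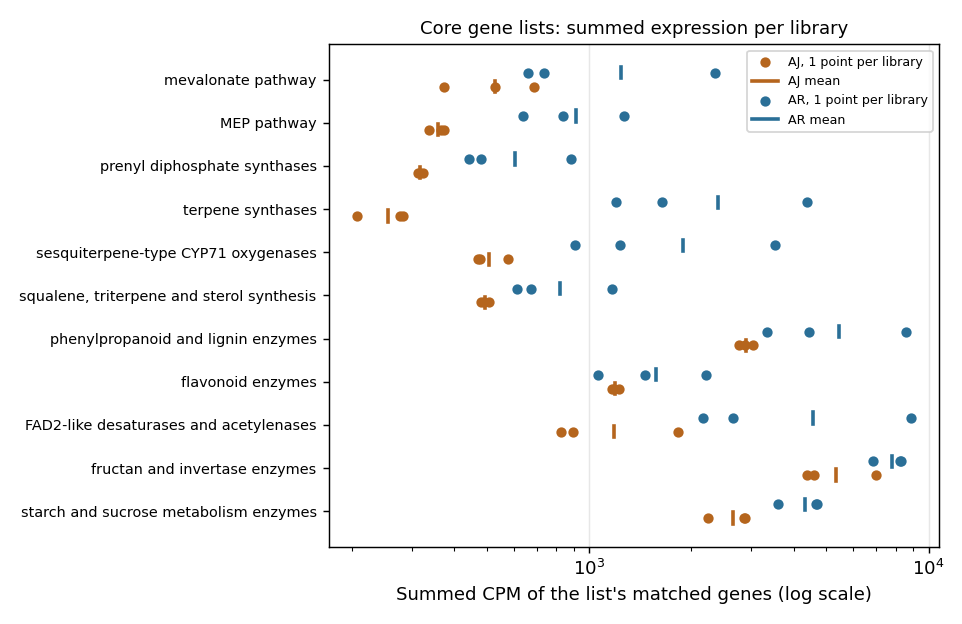
Summed CPM of the matched genes of each core list on a log x axis, with 1 point per library (AJ and AR, n = 3 each) and a vertical bar at each group's mean. Terpene synthases show the widest gap, 255 CPM on average in AJ and 2410 CPM in AR, while the flavonoid, mevalonate and fructan lists overlap between the groups.

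Of 87 tested genes matched as phenylpropanoid and lignin enzymes, 23 were higher in AR, none was higher in AJ and 64 did not pass. Adjusted over the list alone, 23 were higher in AR and 1 higher in AJ. The members with the smallest adjusted p were 2 acyltransferases that entered through the ortholog name shikimate O-hydroxycinnamoyltransferase, while their protein names point to alkaloid acetyltransferases. The first (SALAT, TRINITY_DN23748_c1_g1) had 9.89 ± 2.71 CPM in AJ and 134 ± 31.3 CPM in AR (SD, n = 3), a log2 fold change of -3.76 ± 0.31 (SE, adjusted p = 0.0052). The second, vinorine synthase-like (TRINITY_DN12449_c0_g1), had a log2 fold change of -8.71 ± 1.09 (SE), which was -7.99 without AR replicate 2 and, without AJ replicate 1 or 3, -9.31 and -8.05, where it did not pass. The list passed by camera (adjusted p = 0.0026) and had an adjusted p = 0.57 with an estimated correlation. Without AR replicate 2, the library that stood apart, its adjusted p was 0.15.

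Flavonoid enzymes had called members in both directions, near the shares of all tested genes. Of 52 tested members, 6 were higher in AJ, 4 were higher in AR and 42 did not pass, and 6 and 5 passed adjusted over the list alone. Over all 44406 tested genes, 4577 were higher in AJ and 3385 higher in AR. The type III polyketide synthase PKSA (TRINITY_DN16776_c4_g1), which entered through the ortholog name chalcone synthase, was at least 1760-fold higher in AJ against the floor of 3 counts over the group (adjusted p = 0.0033), or at least 1110-fold without AR replicate 3. The flavonoid 3',5'-hydroxylase CYP75A1 (TRINITY_DN21439_c0_g1), an enzyme of B-ring hydroxylation, had 9346 counts over the AR libraries and 1 over the AJ libraries, a ratio of 12400 with an exact 95% counting interval of 2230 to 490000. Without AR replicate 2 that ratio was 8050 (interval 1440 to 318000). Without AJ replicate 2, which held the AJ count, the gene was at least 2730-fold lower in AJ. As a list the flavonoid enzymes gave an adjusted p = 0.95, with a median log2 fold change of 0.01 and a mean of -0.09.

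Among FAD2-like desaturases, the family that also includes the acetylenases of polyacetylene synthesis, 2 of 15 tested members were higher in AR and 13 did not pass, and the same 2 passed adjusted over the list alone. They were TRINITY_DN22544_c1_g1, at 159 ± 36.6 CPM in AJ and 588 ± 196 CPM in AR (SD, n = 3), and TRINITY_DN26219_c0_g2, at 160 ± 19 CPM in AJ and 935 ± 526 CPM in AR (SD, n = 3). Their log2 fold changes were -1.89 ± 0.32 and -2.55 ± 0.45 (SE). The list did not pass as a whole (median log2 fold change -1.20, adjusted p = 0.11). Of all 44406 tested genes 3385 were higher in AR, and 2 of 15 members do not set the list apart.

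Carbohydrate enzymes were mixed. Of 36 tested fructan and invertase enzymes, 5 were higher in AJ, 6 were higher in AR and 25 did not pass, and 6 and 7 passed adjusted over the list alone. An alkaline/neutral invertase, CINV1 (TRINITY_DN28166_c1_g1), had 7.97 ± 2.13 CPM in AJ (SD, n = 3) and no count in AR, at least 128-fold higher in AJ. A second one, INVB (TRINITY_DN32779_c5_g5), was lower in AJ with a log2 fold change of -1.55 ± 0.22 (SE). Of 104 tested starch and sucrose enzymes, 10 were higher in AJ, 15 were higher in AR and 79 did not pass, and 12 and 18 passed adjusted over the list alone. A sucrose synthase-type gene (TRINITY_DN20934_c0_g1) had a log2 fold change of 6.61 ± 0.69 (SE), or 7.73 without AR replicate 3, and SUS6 (TRINITY_DN31338_c0_g2) one of 2.99 ± 0.37 (SE), both higher in AJ. The lists gave adjusted p = 0.80 and adjusted p = 0.19.

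Among the lists for stress, growth and other tissues, cytosolic ribosomal proteins and pathogenesis-related proteins passed by camera, both in the direction lower in AJ. Their summed levels overlapped between the groups. Ribosomal genes summed to 18400 ± 1330 CPM in AJ and 21400 ± 3170 CPM in AR (SD, n = 3). Pathogenesis-related genes summed to 7760 ± 3900 and 8280 ± 1050 CPM. In both lists a smaller share of members was called than the 17.9% of all tested genes. Of 289 tested ribosomal protein genes, 15 were higher in AJ, 30 were higher in AR and 244 did not pass, with 14 and 27 adjusted over the list alone. The gene with the smallest adjusted p, RPS9C (TRINITY_DN14161_c0_g1), had a log2 fold change of -2.58 ± 0.23 (SE). The list's median was -0.38, with an adjusted p of 0.0089 and an adjusted p = 0.62 with an estimated correlation. Of 92 tested pathogenesis-related genes, 1 was higher in AJ, 6 were higher in AR and 85 did not pass, with none and 2 adjusted over the list alone. A Bet v I type allergen fragment (TRINITY_DN24716_c0_g3) had a log2 fold change of -4.00 ± 0.61 (SE). That list had an adjusted p of 0.013 and an adjusted p = 0.57 with an estimated correlation. Without AR replicate 2 the ribosomal list had an adjusted p of 0.095 and the pathogenesis-related list one of 0.23. The ribosomal list passed in 16 of 19 other settings (range 3.9e-06 to 0.14), also failing with the strict filter (adjusted p = 0.06). The pathogenesis-related list passed in 12 (range 0.0065 to 0.25), also failing in the 3 TPM fits (0.063 to 0.065) and without AJ replicate 2 or 3 (0.054 and 0.25). Against annotated genes only, a background chosen after the data were seen, both had an adjusted p of 0.14.

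The remaining lists of this kind did not pass. Jasmonate synthesis and JAZ genes had 1 member higher in AJ and 2 higher in AR of 43 (adjusted p = 0.18), none and 1 adjusted over the list alone, led by TIFY4A (TRINITY_DN18044_c2_g2) at a log2 fold change of -2.93 ± 0.47 (SE). Heat shock proteins and chaperones had 18 and 24 of 262 (adjusted p = 0.17), and 18 and 19 adjusted over the list alone, led by a DnaJ protein (TRINITY_DN27328_c0_g1) at 2.19 ± 0.19 (SE). LEA, dehydrin, oleosin and storage proteins had 3 and 6 of 34 (adjusted p = 0.15), and 3 and 8 adjusted over the list alone. There an oleosin 1-like gene (TRINITY_DN13699_c0_g1), an oil body protein, had 7.07 ± 5.76 CPM in AJ and 372 ± 42.4 CPM in AR (SD, n = 3), with an AJ mean of 4.07 CPM without AJ replicate 1. Photosynthesis proteins, included as markers of green tissue, had 2 and 5 of 51 (adjusted p = 0.15), and 1 and 5 adjusted over the list alone. One chlorophyll a-b binding protein (TRINITY_DN21373_c0_g3) was at least 75.8-fold higher in AJ. Histones and cyclins had 10 and 14 of 135 by both counts (adjusted p = 0.18). Their first gene (TRINITY_DN25064_c0_g1) is a cyclin-dependent kinase F-4 taken in by its name, at 2.65 ± 0.29 (log2 fold change, SE).

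Cell wall enzymes had 8 members higher in AJ and 18 higher in AR of 154 (adjusted p = 0.058), and 8 and 17 adjusted over the list alone. The polygalacturonase ADPG2 (TRINITY_DN32430_c0_g3), a pectin-degrading enzyme, was at least 184-fold higher in AJ. Vascular and cork markers had 3 and 3 of 55 (adjusted p = 0.35), and 3 and 2 adjusted over the list alone. Among them a CASP-like protein 1D1 (TRINITY_DN13492_c0_g1), of the family of Casparian strip membrane proteins, had 0.0942 ± 0.0796 CPM in AJ and 586 ± 272 CPM in AR (SD, n = 3), with an AJ mean of 0.0484 CPM without AJ replicate 2. WRKY transcription factors had 5 and 2 of 91 (adjusted p = 0.95, median log2 fold change 0.03), and 3 and 2 adjusted over the list alone. Their first gene (TRINITY_DN21666_c0_g2), annotated as the ubiquitin hydrolase UBP12 and matched through its ortholog name, was at least 27.9-fold higher in AJ. AP2/ERF factors had 5 and 12 of 125 (adjusted p = 0.14), and 5 and 10 adjusted over the list alone. There ERF3 (TRINITY_DN25649_c0_g4) had 340 counts over AJ and 1 over AR, a ratio of 256 with an exact 95% counting interval of 45.7 to 10100, and without AR replicate 1 it was at least 59.4-fold higher in AJ.

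More transposable element genes were higher in AJ than in AR. Of 968 tested members, 172 were higher in AJ, 70 were higher in AR and 726 did not pass, and 201 and 89 passed adjusted over the list alone. Their median log2 fold change was 0.43. Of the 14915 tested genes without annotation, 2539 were higher in AJ and 936 higher in AR, with a median log2 fold change of 0.53. Of the 29491 annotated genes, 2038 were higher in AJ and 2449 higher in AR, with a median of -0.16. The split of transposable elements was thus close to that of genes without annotation and is not particular to this list. By camera the list had an adjusted p = 0.053, while fry, which tests only whether a list moves one way, gave an adjusted p of 0.026. Its adjusted p = 0.57 with an estimated correlation, and on log2(TPM + 1) values its direction turned (adjusted p = 0.87). It passed camera higher in AJ in 8 of 19 other settings, among them the strict low-count filter (adjusted p = 3.6e-09) and a background of annotated genes chosen after the data were seen (adjusted p = 0.00028). A reverse transcriptase domain gene (TRINITY_DN22197_c0_g6) had 60.2 ± 16.6 CPM in AJ and 0.765 ± 0.146 CPM in AR (SD, n = 3), a log2 fold change of 6.28 ± 0.34 (SE, adjusted p = 0.0032). With genes at 0 to 3 counts in a group set to their bound or counting ratio, no list's median changed at 2 decimals.

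The largest annotated differences, taken by rule from 797 genes higher in AJ and 1353 higher in AR, included several genes outside these lists. Higher in AJ with no count in AR were the proline transporter PROT2 (TRINITY_DN21618_c1_g1, at least 740-fold), the receptor-like kinase TMK4 (TRINITY_DN21922_c2_g4, at least 646-fold) and a ribonuclease H protein (TRINITY_DN27510_c1_g1, at least 466-fold). The same held for AGO4A (TRINITY_DN29164_c4_g1, at least 430-fold), an Argonaute protein of small RNA-guided silencing. PROT2 was even across AJ at 46.3 ± 1.97 CPM, while TMK4 varied at 42.0 ± 34.2 CPM and the ribonuclease H protein at 32 ± 37.5 CPM (SD, n = 3). Without AJ replicate 2 TMK4 was at least 391-fold higher, and without AJ replicate 1 the ribonuclease H protein at least 165-fold. On log2(TPM + 1) values neither passed (adjusted p = 0.055 and 0.15), nor did TMK4 with group variance weights (adjusted p = 0.082). An RNA-directed RNA polymerase L fragment (TRINITY_DN12795_c2_g10), whose best protein match is from a plant virus, was at least 651-fold higher in AJ at 41.4 ± 16.9 CPM. Higher in AR with no count in AJ were the co-chaperone FKBP62 (TRINITY_DN28915_c0_g2, at least 1430-fold) and a beta-amyrin 28-oxidase fragment (TRINITY_DN14869_c0_g2, at least 1330-fold). Both varied within AR, at 62.9 ± 80.3 and 63.0 ± 77.3 CPM (SD, n = 3), and were at least 350-fold lower in AJ without AR replicate 3 and at least 402-fold lower without AR replicate 2, respectively.

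None of the most abundant genes passed the test. An HSP70 gene (MED37C, TRINITY_DN30791_c0_g1) was the most abundant in both groups, at 10800 ± 1110 CPM in AJ and 9170 ± 1980 CPM in AR (SD, n = 3), with a log2 fold change of 0.24 ± 0.37 (SE, adjusted p = 0.69). A gene without a named protein (TRINITY_DN21235_c0_g1) had a log2 fold change of -0.17 ± 0.46 (SE), a root allergen protein-like gene (TRINITY_DN25657_c2_g1) one of 0.14 ± 0.46 (SE), and a vacuolar-processing enzyme (TRINITY_DN19772_c4_g1) one of -0.25 ± 0.39 (SE). Of the 46 different genes named by rule, 42 passed the test, and these 4 did not. The 42 were chosen for passing or for the smallest adjusted p of a list, so their number is no separate evidence. Leaving out AJ replicate 1, 2 or 3 left 10, 4 and 10 of the 46 past the threshold, and the highest adjusted p among the 42 was then 0.10.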

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

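The added alternatives (variance weights, summed genes, narrow lists and annotated background) were chosen after the data were seen. The 7962 called genes, and those past 2-fold, stayed within 1.5 times under RLE and upper-quartile scaling, limma-voom with and without group weights, the 3 TPM fits and, for the first count, the test against a 1.5-fold change. Of the 7962, those scalings and limma-voom fits also called 7233 to 7757, but the TPM fits only 4757 to 5491. The counts were 4521 and 4504 with no low-count filter (84109 genes tested), 4518 and 4158 with the strict filter (26468 tested), and 13255 and 11751 with DESeq2. Summing counts per component gave 3574 calls of 28376 and per protein hit 2070 of 20527, with fewer units tested. The cause was not tested for DESeq2 or the filters. Leaving out 1 library gave 55 to 11371 calls and 55 to 10952 past 2-fold, with the low values without AJ replicate 1, 2 or 3 (250, 55 and 117), where 2 AJ libraries set against the more variable AR libraries are left, and the cause was not tested. Without AR replicate 1, 2 or 3 there were 10344, 11371 and 8263. All of the 55 and 117 calls and 249 of the 250 were among the 7962. The median log2 fold change of tested genes was -0.02 under TMM, 0.08 under upper-quartile scaling, 0.11 on log2(TPM + 1) and 0.21 with a pseudocount of 0.1.

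Deviations from the group means correlated at 0.00, 0.13 and 0.19 between AJ and AR libraries of number 1, 2 and 3. AJ replicates 2 and 3 correlated best with the AR library of their own number, and AJ replicate 1 did not. Pairing by replicate number was therefore neither shown nor excluded. With the replicate block 607 genes were called, all 607 past 2-fold, and 22 of the named genes passed in place of 42. Camera with an estimated correlation passed 0 lists. The lowest adjusted p there, 0.57, was shared by several lists. Their estimated correlations differed, at 0.00019 for the MEP pathway, 0.028 for CYP71 oxygenases and 0.21 for terpene synthases. So the value 0.57 does not by itself show that the members of a list are correlated. Fry passed 2 lists, CYP71 oxygenases, which was the only one of the 6 camera lists to pass it, and transposable elements. The lists passing ranged from 3 (without AR replicate 2) to 12 (without AR replicate 3). Terpene synthases, CYP71 oxygenases and prenyl diphosphate synthases passed camera at the preset correlation in all 19 other settings run. These settings reuse the same libraries, so they are not independent support. Other divisions of the libraries gave up to 12 passing lists at this correlation, against 6 for the real one. Of lists that did not pass in the main test, photosynthesis proteins and cell wall enzymes passed in 7 of these each, the mevalonate pathway in 5, FAD2-like desaturases in 3, LEA and storage proteins in 2, and the MEP pathway and AP2/ERF factors in 1 each. Named genes past the threshold ranged from 4 to 42 when a library was left out. Across settings with all AJ libraries and no block, 8 of 542 values of the 42 genes lost the call, with adjusted p up to 0.15. The 42 were chosen by their adjusted p in the main fit of the same libraries, so this is not independent support.

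Some lists and genes that did not pass in the main test changed sign, in settings where they did not pass either. Flavonoid enzymes pointed higher in AJ with no filter (adjusted p = 0.71), limma-voom (0.78), group weights (0.92), the 3 TPM fits (0.72 each), fry (0.53), annotated genes (0.57) and without AJ replicate 1, 2 or 3 or AR replicate 2, while the adjusted p ranged from 0.63 to 0.88 over the 6 fits that left out a library. WRKY factors did so with no filter (0.47), limma-voom (0.95), group weights (0.92), TPM (0.55, 0.64 with a pseudocount of 0.1, 0.52 unfiltered), fry (0.56), annotated genes (0.56) and without the same libraries (range 0.38 to 0.88). Fructan and invertase enzymes did so with the strict filter (0.74), fry (0.59), annotated genes (0.78) and without AJ replicate 2 (range without a library 0.63 to 0.93). Transposable elements, which passed camera higher in AJ in 8 of the 19 settings, pointed lower in AJ on log2(TPM + 1), filtered or not (0.87). TRINITY_DN21235_c0_g1 had a log2 fold change of 0.16 in the 3 TPM fits, and ranged from -0.47 to 0.06 without a library, above 0 without AJ replicate 3 or AR replicate 3. TRINITY_DN25657_c2_g1 ranged from -0.09 (without AR replicate 3) to 0.62.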

Other observations

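The pathway tests, the choice of virus-like genes, the random placement of genes, and the tests of other divisions for gene counts, of assembled copies, of AR replicate 2 and of genes without a hit were chosen after the values they bear on were seen. Of 246 one-sided Fisher's exact tests on 123 KEGG pathways (background 9604 tested genes with a pathway, adjusted over all tests), 7 pathways were enriched among genes higher in AR and 5 among genes higher in AJ. Among genes higher in AR were stilbenoid, diarylheptanoid and gingerol biosynthesis (12 genes, 3.12 expected, adjusted p = 0.0031), pyruvate metabolism (33 genes, 16.6 expected, adjusted p = 0.0044), arachidonic acid metabolism (13 genes, 4.1 expected, adjusted p = 0.0052) and porphyrin metabolism (18 genes, 7.3 expected, adjusted p = 0.0069). The others were phenylpropanoid biosynthesis (adjusted p = 0.0063), glycolysis (adjusted p = 0.032) and sesquiterpenoid and triterpenoid biosynthesis (9 genes, 2.94 expected, adjusted p = 0.038). Terpenoid backbone and monoterpenoid biosynthesis did not pass (adjusted p = 0.064 each). These Fisher tests treat genes as independent, and no pathway passed camera with an estimated correlation. Among genes higher in AJ were galactose metabolism, pentose and glucuronate interconversions, pyrimidine metabolism (38 genes, 22.7 expected, adjusted p = 0.027), ascorbate and aldarate metabolism (27 genes, 11.5 expected, adjusted p = 0.0031) and amino sugar metabolism (42 genes, 22.1 expected, adjusted p = 0.0031). One ortholog name, UDP-sugar pyrophosphorylase, was carried by 88 tested genes, of which 24 were higher in AJ and 11 higher in AR. Of those 35 genes, the protein name was that enzyme for 2 and a retroelement for 22. Without retroelement-like genes and others that carry this ortholog name alone, no pathway was enriched among genes higher in AJ and 5 were among genes higher in AR. Sesquiterpenoid and triterpenoid biosynthesis then no longer passed (Fisher's exact test, adjusted p = 0.059).

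Several genes whose best protein match is from a plant virus had counts in AJ and almost none in AR. A nucleoprotein gene (TRINITY_DN1277_c0_g1), matched to Mirafiori lettuce virus, had 714, 3514 and 2293 counts in the AJ libraries and 1 count over AR. The ratio was 4910 with an exact 95% counting interval of 882 to 194000 (log2 fold change 11.83, adjusted p = 0.0057 by edgeR). It rests on the 1 count in AR replicate 3, and without that library only a lower bound could be given. All 3 RNA polymerase L fragments of component DN12795, matched to lettuce necrotic yellows virus, had counts in every AJ library and none in AR, at least 90.7-, 99.2- and 651-fold higher in AJ. By contrast, 3 capsid protein genes matched to soybean chlorotic mottle virus were counted in both groups and did not pass (adjusted p = 0.44, 0.65 and 0.62).

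Other divisions of the 6 libraries into 3 and 3 were counted for each test across genes. The real division gave 7962 called genes and 7600 past 2-fold, and each of the other 9 gave 0, so 1 of 10 divisions reached the real value. For the gene lists, 7 of the 10 divisions gave as many passing lists as the real 6, and the highest of the others gave 12. With 10 divisions the share can never fall under 0.05.

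Among called genes, those found in 1 group only were frequent, 1893 in AJ and 697 in AR with at most 3 counts over the other group. They were short (median 529 and 619 bases against 904 for other tested genes). Genes that did not pass the test were not counted, so the imbalance holds for called genes only. Whether it reflects the wider spread within AR, which bears on what passes, was not tested. The higher depth of the AJ libraries is argued against as the cause of the imbalance. Thinning every library to the lowest total left a ratio of called AJ-only to called AR-only genes of 2.45. Diverged copies of a gene that the assembly kept apart may account for part of the pattern, and 59 components held both an AJ-only and an AR-only gene. That number lay below the 68 to 111 found when the kinds were dealt at random over these 2590 genes and above the 17 to 53 found when as many genes were placed at random among those tested, and fragments of one transcript share a component, so this stays open. After summing counts, 20.8% of the 1503 components with such a gene and another tested gene were still called, which excludes neither copies nor dilution by more abundant neighbours. The other 840 genes had no tested neighbour in their component, and 705 of their components were called after summing, which says little of copies, and a difference in gene content between the plants was not tested.

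Single AR libraries held many genes with at least 50 counts that had at most 1 count in each of the other AR libraries, 370, 471 and 357 in AR replicates 1, 2 and 3 against 11, 10 and 15 in the AJ libraries. Lower depth in AR is argued against, since after thinning AR libraries still had 38.3 times as many such genes as AJ libraries (371 against 9.67 on average). For the 477 of these 1198 genes with a hit, the best hits argue against material from outside the daisy family as main source. Of these hits, 86.4% lay in the daisy family (78.9% to 90.9% per library), against 89.8% of all tested genes with one. Material of another daisy-family plant would also give daisy-family hits, so it stays open. For the 721 without a hit, material of any other organism stays open, and 15.8% of them had at least 10 counts in an AJ library. Plants of AR that carry different gene copies, while AJ plants resemble each other, is a candidate explanation that stays open. It predicted components with genes private to different AR libraries above chance, and the 25 found lay below the 38 to 63 of random deals over libraries and at the upper end of the 3 to 25 of random placement, again with fragments of one transcript in one component.

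Terpene synthases and CYP71 oxygenases lower in AJ are the pattern closest to the study's question. Copies kept apart by the assembly would leave similar totals in both groups, but the log2 difference of summed counts was -3.02 for terpene synthases, with 282 CPM in the highest AJ library and 1200 CPM in the lowest AR library, and -1.64 for CYP71 oxygenases, with 578 and 905 CPM. For terpene synthases AR replicate 2 alone is argued against as well, since the difference without it was -2.48, with no overlap between groups. For CYP71 oxygenases the difference without it was -1.06, also with no overlap. However, both CYP71 sums include the triterpene-type CYP716B2, with 71.2, 1010 and 187 CPM in AR replicates 1, 2 and 3. They were not repeated without that gene, so AR replicate 2 stays open for CYP71 oxygenases. A shift of all annotated genes does exist (median log2 fold change -0.16, against 0.53 for genes without annotation), yet against annotated genes only the larger adjusted p of these lists by camera was 0.037. Other divisions of the libraries gave up to 12 passing lists, against 6 for the real one, so the camera calls alone are weak support. AJ copies without annotation text remain possible, the list calls are lost with an estimated correlation, and a difference between the plants in species, age or state was not tested, so a lower expression of volatile terpenoid synthesis in AJ is a hypothesis. Metabolite levels, which would bear on it, were not analysed here.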
